A study of Escherichia coli with 4 samples.

How the data were processed

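RNA was sequenced from Escherichia coli TOP10 carrying pHERD30T, an arabinose-inducible plasmid vector, with or without induced expression of LL37, a human antimicrobial peptide. The labels give growth in LB medium at 37 °C, with or without air. Per the labels, RNA was isolated with TRIzol, treated with DNase I for 30 min and depleted of ribosomal RNA with a Ribo-Zero kit. It was then fragmented to about 200 bp, copied into cDNA from random hexamers and read on a HiSeq 2000 instrument. The labels name no inducer, growth phase or strand protocol. The aligner, the counting tool and the genome build are not given in the sources used here. Reads from overlapping or antisense genes can therefore not be told apart.

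The deposited table gives 1 RPKM value (reads scaled by gene length and library size) per gene and library, for 3918 genes with DH10B locus tags. Its title names the unit, and the values fit it. Each value multiplied by the coding length is a whole multiple of a fixed step in its library, so the reads per gene and the read total behind the RPKM were recovered from the steps. Among the low values, the share within 0.05 reads of a whole number was 100% in the aerobic control and the anaerobic LL37 library, 99.97% in the aerobic LL37 library and 99.96% in the anaerobic control. Coding length was taken from the protein length in the table, and it equalled the coordinates for the 689 genes whose coordinates are written in full. The other coordinates are rounded and were not used. Columns whose names hold CK were assigned to the controls, as in the sample titles. The remaining pair of columns, whose prefix LA stands in no label, was assigned to the LL37 cultures. An MG1655 reference table served for names only: 3303 genes matched by symbol, 505 by synonym and 110 not at all. Reads shared between near-identical genes, such as gadA and gadB, cannot be assigned with certainty, and their values are uncertain to that extent.

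Each of the 4 groups (aerobic or anaerobic, control or LL37 induced) holds 1 library, so there are no replicates and no spread between cultures is known. The read totals behind the RPKM were 4345029 for the aerobic control, 3383946 for aerobic LL37, 6149126 for the anaerobic control and 3716175 for anaerobic LL37. For a gene of 1 kb, a count of 0 allows up to 0.690, 0.887, 0.488 and 0.807 RPKM in the same order (3 reads per library). Where a library had 0 reads, a fold is given as a lower bound against that floor, and no fold is given where both libraries held at most 3 reads. Intervals are 95% exact (Clopper-Pearson) binomial intervals on recovered reads. Intervals and floors cover counting error only.

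Gene lists, comparisons, the size and percentile rules and most alternatives were fixed before the data were examined, and what was added later is named as such. Log2 ratios were taken on RPKM + 1 for the 2096 genes with a mean of at least 10 RPKM over the 4 libraries. The size rule was a 2-fold difference. Scaling moved the median of all genes by more than 0.1 on the log2 scale, so ratios and folds are given relative to the median tested gene unless stated otherwise. Folds of single genes were computed on RPKM without the added 1. Of the 46 gene lists fixed, 42 had at least 4 tested members. The median of each was placed among 10000 random lists matched on mean RPKM decile. These draw genes independently, whereas genes of an operon move together (SD within operons 0.88, against 1.97 over all genes, for LL37 with air). Lists made of operons can therefore pass more often by chance than the percentiles imply. If genes varied independently, 2.1 of the 42 lists would pass each threshold by chance in a comparison. No p was computed for a comparison of 2 libraries. The one test was an additive limma fit over the 4 libraries, with terms for LL37 and oxygen, 1 residual degree of freedom, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Its prior degrees of freedom were infinite, so the variance was pooled over genes along the trend. It assumes that LL37 acts alike in both oxygen conditions.

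Named genes came from a fixed rule. Per comparison, these were the 10 highest and 10 lowest ratios among genes with a symbol and at least 50 RPKM in the higher library. They also include the 8 highest and 8 lowest differences of LL37 ratios and, for the limma fit, the 10 genes per term and direction with the smallest adjusted p. Up to 4 members with the largest ratios and up to 2 with the highest RPKM were taken from each list. Of 23 genes to be reported always, 21 are in the table. The remaining pair, recA and ompT, was not analysed here.

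The alternatives were pseudocounts of 0.1 and 10 RPKM, no filter or a mean of at least 50 RPKM, and scaling by the median of ratios, by the sum of RPKM, by that sum without the top 1% of genes, or by quantile normalization. A 4-fold size rule, limma without a trend, robust limma, a threshold of 0.10 and lists without shared members were also planned. Added after the data had been seen were centring on the median gene, the same for genes of at least 600 bp, random lists matched on length as well, lists without members at the read floor in both libraries, and a rule on recovered reads (at least 20, exact interval past 2-fold). That last rule had been planned for a table with read counts, which was not used here.

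The steps were tested on simulated data with noise of SD 0.4 on log2 and 200 changed genes. The size rule recovered 93.3% and 95.6% of the 4-fold changes in the aerobic and anaerobic comparisons, and called 9.18% and 9.02% of the unchanged genes. The limma fit recovered 59 of 90 4-fold and 80 of 80 16-fold changes and called 0 unchanged genes. All 20 raised lists and 0 of 20 unchanged lists passed the percentile rule. The simulated libraries shared the same base profile, with genes varying independently and without a shift in scale or a scarcity of short genes. In the real libraries the SD of ratios within operons was 0.81 to 1.71. The simulated rates therefore show that the steps run as intended, not how often they err on these data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.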

Results

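The data are 4 transcriptomes of Escherichia coli TOP10, a cloning strain, grown with or without air and with or without induced expression of the human antimicrobial peptide LL37. Each combination is 1 library. The aerobic control carried the vector under a label without LL37, whereas the anaerobic control carried the LL37 plasmid without induction, so the aerobic comparison also differs in the plasmid. Genes in the table held 1251322 reads in the aerobic control, 233682 in aerobic LL37, 408079 in the anaerobic control and 372966 in anaerobic LL37. These were 28.8%, 6.91%, 6.64% and 10.0% of the read totals behind the RPKM. The ribosome hibernation factor gene rmf was the most abundant transcript in the aerobic control (35596 RPKM), the envelope stress gene cpxP in aerobic LL37 (8042), the ribose gene rbsD in the anaerobic control (4931) and the porin gene ompA in anaerobic LL37 (5321). The 10 most abundant genes took 18.1%, 20.01%, 21.5% and 14.3% of the reads in genes.

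Across genes, log2 RPKM was most alike between the anaerobic libraries (Pearson r 0.79), and less so between the aerobic libraries (0.50). It was 0.16 between the controls and 0.15 between the LL37 libraries. Genes are not independent replicates, so these are descriptions only. Short genes were scarce in both anaerobic libraries. The 155 tested genes below 300 bp had a median of 99.3 RPKM in the aerobic control and 20.5 in aerobic LL37, against 2.55 and 2.09 in the anaerobic control and LL37 libraries, where 34.8% and 41.9% of them had 0 reads. Every oxygen comparison of short genes, ribosomal protein genes included, carries this difference in composition. The filter on mean RPKM favours genes high in the aerobic control, where the sum of RPKM was largest (418889, against 70391 to 100986 in the other libraries). Part of the gap to that library can therefore come from the filter.

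**Figure D1:**
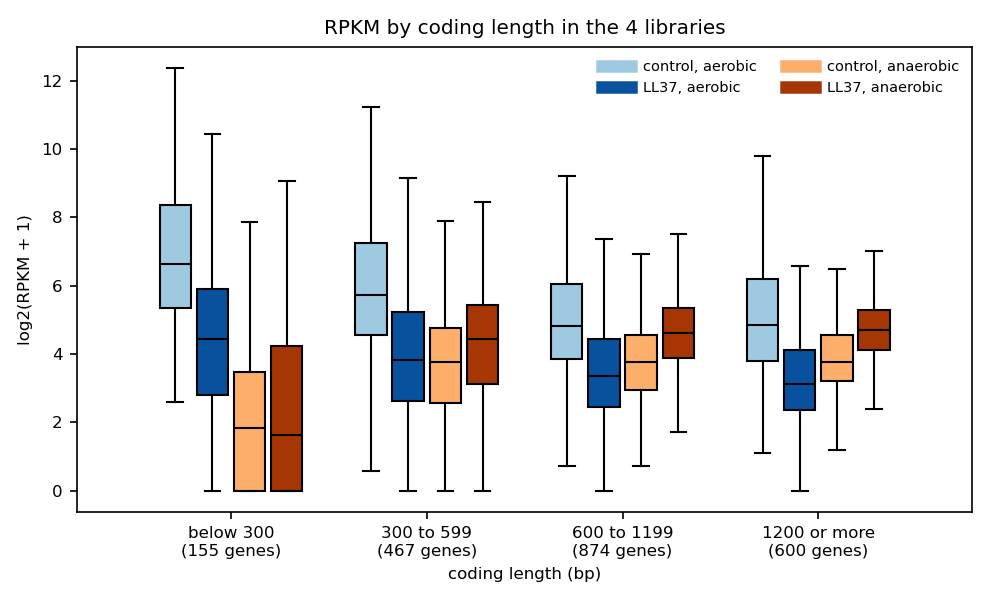
Box plots of log2(RPKM + 1) for tested genes in 4 classes of coding length (bp), 1 box per library, with the median as a line, the box from the lower to the upper quartile and whiskers to the last value within 1.5 box lengths. In genes below 300 bp the median was 99.3 and 20.5 RPKM in the aerobic libraries and 2.55 and 2.09 RPKM in the anaerobic libraries.

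The first comparison sets the aerobic LL37 library against the aerobic control, which also differs in the plasmid. The phage shock genes, which respond to damage of the inner membrane, were the highest in the aerobic LL37 library: all 7 of 7 tested members were at least 2-fold higher, with a median of 6.94 on log2, above every matched random list (percentile 100). List members counted as higher or lower differ by at least 2-fold relative to the median gene. Counts of list members cover tested genes only. The membrane-binding effector gene pspA (ECDH10B_1421) was at 129.7 RPKM in the control and 5377 with LL37, 124-fold [95% interval 112 to 138] higher. Its operon partners pspB (323-fold [95% interval 195 to 579]), pspC (240.0-fold [95% interval 133 to 483]) and pspD (179-fold [95% interval 104 to 338]) had larger ratios. The intervals of pspC and pspD overlap that of pspA. With pspE included, the mean log2 ratio of these 4 partners lay only 0.056 above that of pspA. A distant member of the regulon, pspG, was 65.3-fold [95% interval 38.9 to 118] higher. The activator gene pspF was higher by 1.36 on log2. Besides the phage shock genes, the highest ratios were those of the peptide transporter genes yejE (90.7-fold [95% interval 58.1 to 149.9]), yejF (65.6-fold [95% interval 55.7 to 77.8]) and yejB (63.5-fold [95% interval 41.7 to 101]), ygaV (62.1-fold [95% interval 27.5 to 173]) and the motility repressor gene lrhA (46.8-fold [95% interval 39.6 to 55.7]).

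Several envelope stress lists were higher as well. Of the 28 sigma E genes, which serve outer membrane protein folding and lipopolysaccharide, 15 were higher and 2 lower (median 1.05, percentile 99.99). Among them, bamE was higher by 3.03 on log2, rseA by 2.12 and rpoE by 1.99. Of the 19 genes of the Cpx response to misfolded envelope proteins, 8 were higher and 3 lower (median 0.80, percentile 99.6). Examples were yebE (50.6 RPKM in the control and 752 with LL37), cpxP (1009 and 8042), ldtD (3.87 on log2) and the protease gene degP (123 and 284). The lipopolysaccharide list had 7 of 19 genes higher and 1 lower (median 0.79, percentile 96.7, or 94.8 among lists also matched on length, and 93.2 over members on this list only). The Rcs list (median 1.06, 4 of 7 higher and 3 lower, percentile 93.3) and the BaeSR list (0.44, 2 of 4 higher, percentile 65.2) did not pass the 95th percentile. Nor did the PhoPQ and BasRS list, which covers resistance to cationic peptides (6 of 12 higher, 1 lower, median 0.73, percentile 92.8), although its 11 members on this list only did (median 1.15, percentile 97.7). Heat shock genes had a median of 0.54 with 9 of 24 higher and 4 lower (percentile 99.7). The median was -0.0089 without the filter on low values, still at percentile 99.35, and -0.0051 over genes of at least 600 bp, at percentile 94.9.

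Some lists of uptake and biosynthesis genes were high too. All 8 tested Fur-controlled iron uptake genes, of 32 on the list, were higher (median 2.07, percentile 99.9), with tonB higher by 3.16 on log2. So were 3 of 4 tested zinc and manganese uptake genes (median 1.98, percentile 98.5). Sulfate assimilation and cysteine genes had a median of 2.35 (5 of 8 higher, 1 lower, percentile 99.96), led by the cystine transporter gene tcyP at 3.22. The methionine list had a median of 1.75 (8 of 12 higher, percentile 99.9), whereas 4 other biosynthesis lists stayed inside the thresholds: arginine 0.011 (percentile 25), tryptophan -0.86 (9.42), branched chain amino acids -0.29 (22.9) and purines and pyrimidines 0.45 (70.8). The phosphate starvation list was at -0.68 (percentile 14.5). The multidrug efflux list was at 1.76 (6 of 11 higher, percentile 99.8). Toxin-antitoxin genes had a median of 1.61 (8 of 13 higher, percentile 99.9), with mazF higher by 4.52 on log2. Of the 4 tested arabinose genes, 2 were higher (median 1.89, percentile 98.5; without the filter on low values -0.0025, percentile 72.2). The arabinose uptake gene araE went from 9.24 to 67.1 RPKM and the exporter gene araJ from 1.94 to 8.23, whereas araF was at -0.82 on log2.

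Stationary phase and central metabolism genes lay at the other end. All 28 of 28 tested genes of RpoS, the general stress sigma factor, were lower with LL37, with a median of -4.36 below every matched random list (percentile 0). The DNA-protecting protein gene dps (ECDH10B_0880) was at 8786 RPKM in the control and 9.38 with LL37, 313-fold [95% interval 193 to 548] lower. Likewise ycaC was 171-fold [95% interval 82.8 to 425] lower, the ribosome-associated gene sra 130.2-fold [95% interval 83.3 to 216] lower, and rmf 78.6-fold [95% interval 63.6 to 98.3] lower. With 1160 reads in the control and 0 with LL37, yegP was at least 101-fold lower. The morphogene bolA had 737 and 1 reads, a ratio of 192-fold [95% interval 34.3 to 7585]. Of the 10 acid resistance genes, 8 were lower and 2 higher (median -3.23, percentile 0).

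Several lists of energy metabolism were low as well. Of 16 genes of the citric acid and glyoxylate cycles, 12 were lower and 2 higher (median -3.53, percentile 0.01), with the isocitrate lyase gene aceA at 3824 and 41.9 RPKM. Glycolysis (15 of 16 lower, median -3.06, percentile 0.295), aerobic respiration (11 of 16, -2.08, percentile 0.05) and NADH dehydrogenase I (12 of 13, -1.81, percentile 1.24) were low too. Inside the thresholds were ATP synthase (4 of 9 lower, median -0.79, percentile 55.2), cytochrome bd (3 of 4 lower, -1.46, percentile 32.1) and the hydrogenases (5 higher and 6 lower of 17, -0.19, percentile 12.9). Fermentation genes had a median of -1.78 (11 of 15 lower, percentile 1.23), among them adhE (2625 and 33.6 RPKM) and pflB (874 and 15.1). The list of catabolite-controlled carbon genes had 28 of 43 lower and 0 higher (median -1.80, percentile 0), with gatY lower by 32.3-fold [95% interval 25.8 to 41.1]. Smaller shifts were seen in the OxyR regulon (median -1.60, percentile 1.35), the nitrogen limitation list (-1.24, percentile 0.6) and anaerobic respiration (-0.72, percentile 1.35). The general porin genes ompC and ompF were at -4.60 and -4.97 on log2. The oxygen comparison of the controls has the same aerobic reference. There, medians were similar for iron uptake (2.00), acid resistance (-3.13), citric acid cycle (-3.68), aerobic respiration (-1.92), catabolite-controlled (-1.72) and OxyR genes (-1.55). Between the LL37 libraries these lists stayed inside the thresholds. For them, LL37, the plasmid and a state of the aerobic control cannot be told apart. Other lists also kept their sign between the controls, though inside the thresholds there. Examples were NADH dehydrogenase I (-1.59, percentile 5.75), glycolysis (-2.29, percentile 29.3) and sulfate and cysteine genes (1.45, percentile 92.6). The same limit applies to these lists. The phage shock list was at -0.20 between the controls. In all, 12 of 42 lists lay above the 95th and 11 below the 5th percentile. The median gene was at -1.58 on log2 with LL37 as deposited, so 131 genes were at least 2-fold higher and 1346 lower on the deposited scale, against 543 and 615 relative to the median gene.

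**Figure D2:**
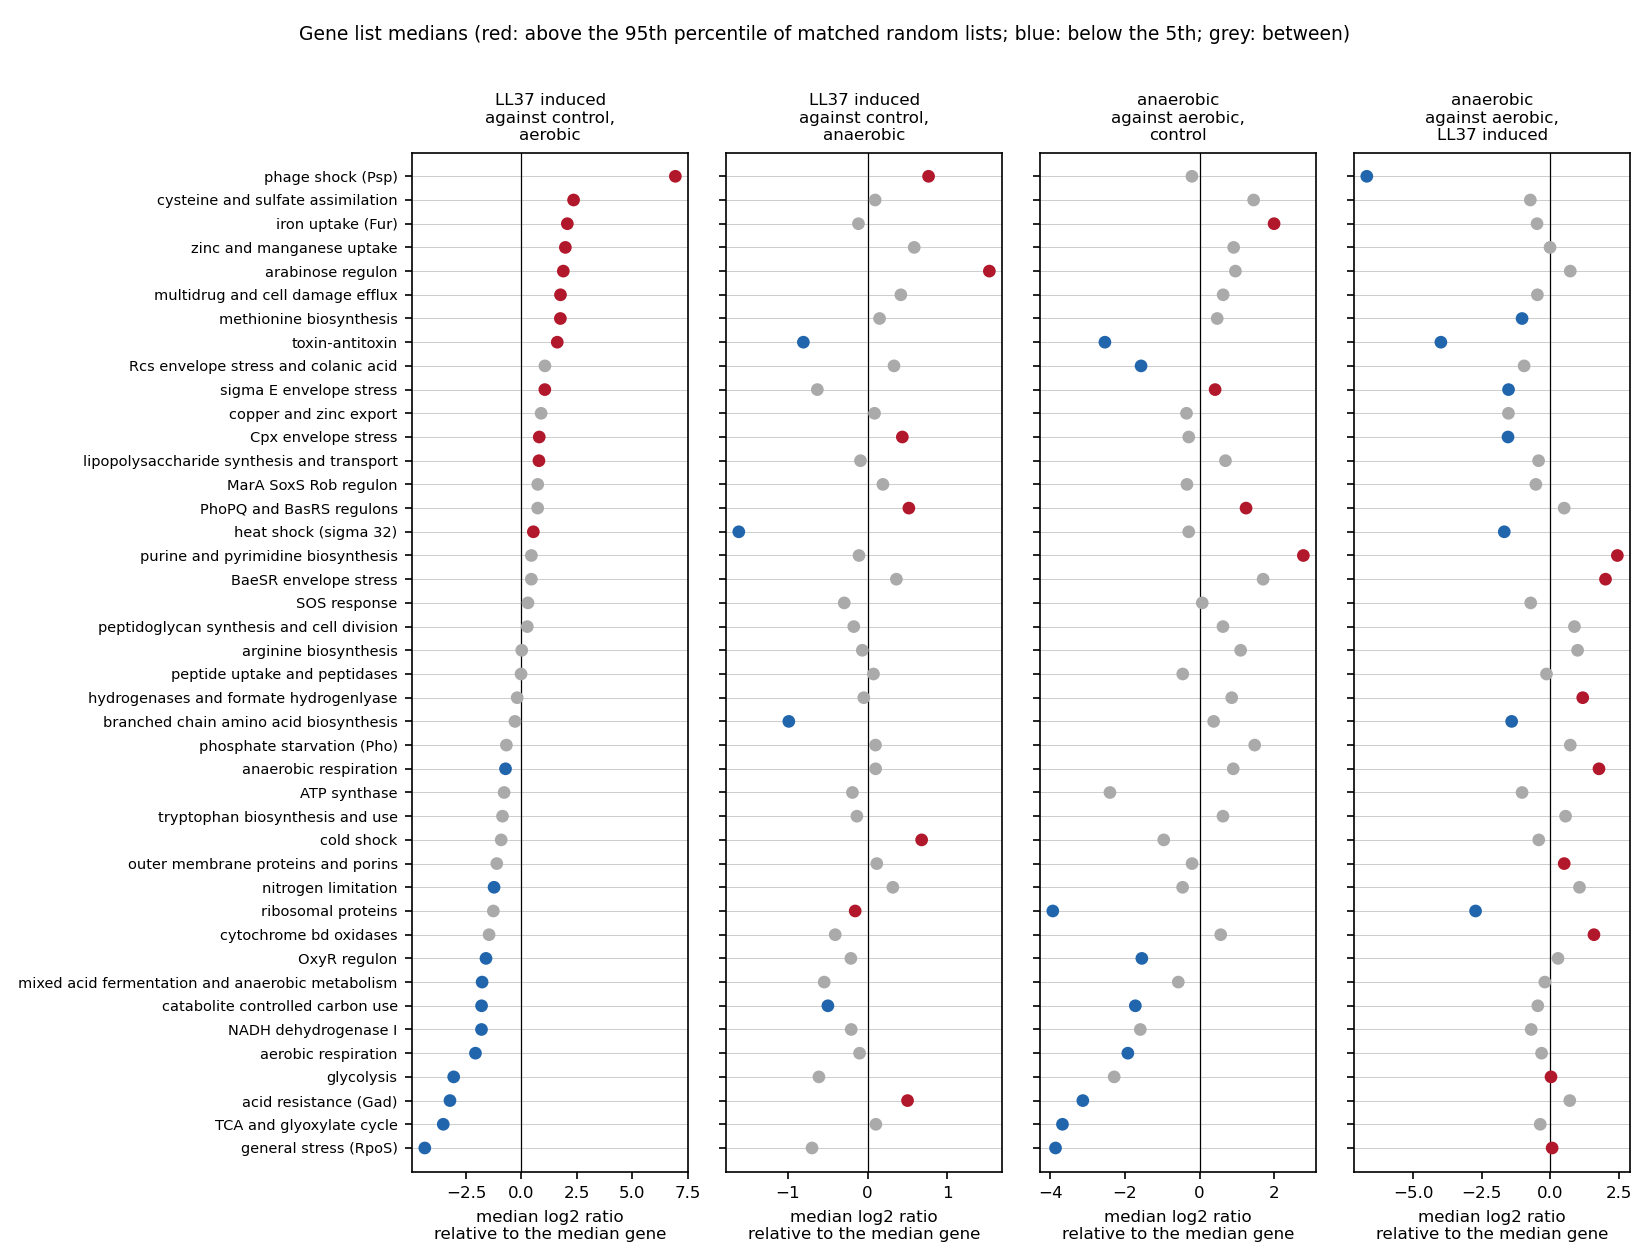
Each point is the median log2 ratio, relative to the median gene, of 1 of 42 gene lists in 1 of the 4 comparisons, red above the 95th and blue below the 5th percentile of matched random lists, with x axes that differ in range. The phage shock median was 6.94 for LL37 with air, and the RpoS median -4.36.

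The next comparison sets LL37 against the control in cells grown without air, where both libraries carried the LL37 plasmid. The arabinose genes were the highest list, with 3 of 4 higher (median 1.53, percentile 99.9). The exporter gene araJ (ECDH10B_0352) went from 4.12 RPKM in the control to 551 with LL37, 76.6-fold [95% interval 53.5 to 114] higher and the highest ratio of all named genes here, and araE from 10.9 to 60.1. The spermidine exporter gene mdtJ was 15.8-fold [95% interval 7.0 to 44] higher, yiiR 14.3-fold [95% interval 7.31 to 31.9] and the cold shock gene cspG 6.62-fold [95% interval 2.8 to 19.1]. Phage shock genes had a median of 0.76 (2 of 7 higher, percentile 99.1), and pspA was at 14.6 RPKM in the control and 56.3 with LL37, 2.21-fold [95% interval 1.62 to 3.04] higher.

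The heat shock list was the lowest: 16 of 24 genes were lower and 2 higher (median -1.62, percentile 0). The disaggregase gene clpB was at 691 and 155 RPKM, 7.78-fold [95% interval 7.37 to 8.22] lower. The chaperone gene dnaK was at 174 and 73.1 RPKM, 4.16-fold [95% interval 3.78 to 4.59] lower, and groL was 5.93-fold [95% interval 5.01 to 7.06] lower, while the protease gene htpX was 3.23-fold [95% interval 2.93 to 3.57] higher. Among genes with at least 50 RPKM in the higher library, low single ratios included wrbA (27.2-fold [95% interval 19.7 to 38.4] lower), dps (17.3-fold [95% interval 9.66 to 34] lower, from 63.2 to 6.41 RPKM), yagE (9.45-fold [95% interval 7.04 to 12.9]), yhcO (8.77-fold [95% interval 6.47 to 12.1]) and nfuA (8.2-fold [95% interval 6.15 to 11.1]). Sigma E genes had 12 of 28 lower and 0 higher (median -0.63, percentile 6.29). That list lay at percentile 3.6 among lists also matched on length and at 0.95 over the 27 members above the read floor (median -0.74), but at 48.1 over the 20 members on this list only (median -0.18). RpoS genes had 9 of 28 lower and 3 higher (median -0.70, percentile 7.84).

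Cold shock genes had a median of 0.68 (3 of 10 higher, percentile 99.7; -0.13 at percentile 71.05 over genes of at least 600 bp). The PhoPQ and BasRS list had 4 of 12 higher (median 0.52, percentile 96.6), with the lipid A modification gene eptA higher by 1.29 on log2 and the magnesium transporter gene mgtA at 0.64. Cpx genes had 6 of 19 higher (median 0.43, percentile 99.6) and acid resistance genes 3 of 10 (median 0.50, percentile 96.9). Ribosomal protein genes had a median of -0.16 (percentile 98.3), which was 0.10 under median-of-ratios scaling (percentile 99.95) and 0.055 under quantile normalization (percentile 82.45). On the low side, the catabolite-controlled carbon list had 17 of 43 lower and 3 higher (median -0.50, percentile 1.76), with rbsD 7.73-fold [95% interval 7.35 to 8.13] lower. The branched chain amino acid list had a median of -0.99 over 5 genes (percentile 1.46). For the toxin-antitoxin list, the median of -0.81 is the value of genes with 0 reads in both libraries, and over the 7 members above the read floor it was 0.20 (percentile 69.4). Of 42 lists, 7 lay above the 95th and 4 below the 5th percentile, where chance would give 2.1 on each side. The 4 low lists include the toxin-antitoxin list. As deposited, the median gene was at 0.81 on log2, with 852 genes at least 2-fold higher and 120 lower, against 255 and 344 relative to the median gene.

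The LL37 ratios in the aerobic and anaerobic comparisons shared little. Across the 2096 genes their correlation was 0.17 (Pearson) and 0.14 (Spearman). Both ratios were at least 2-fold higher for 78 genes, where independent ratios would give 66.1, and at least 2-fold lower for 145, against 101. The arabinose and Cpx lists and the phage shock list were above the 95th percentile in both conditions, and the catabolite-controlled list was below the 5th in both. With air, the arabinose list did not pass under 3 alternatives. Its percentile was 72.2 without the filter on low values, 68.0 with the same sum and 63.5 with that sum without the top 1% of genes. Several phage shock genes differed strongly: the log2 ratio without air minus that with air was -7.48 for pspB, -6.66 for pspC and -6.51 for pspG, next to -7.43 for the formaldehyde regulator gene frmR and -6.51 for yejF. In the other direction, the difference was 7.22 for the glutaredoxin gene grxB, 7.12 for gadB and 7.02 for elaB. Relative to the median gene, the ratio was at least 4-fold larger without air for 332 genes and at least 4-fold smaller for 288, against 1232 and 39 as deposited. With 1 library per group, no difference between the conditions was tested.

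**Figure D3:**
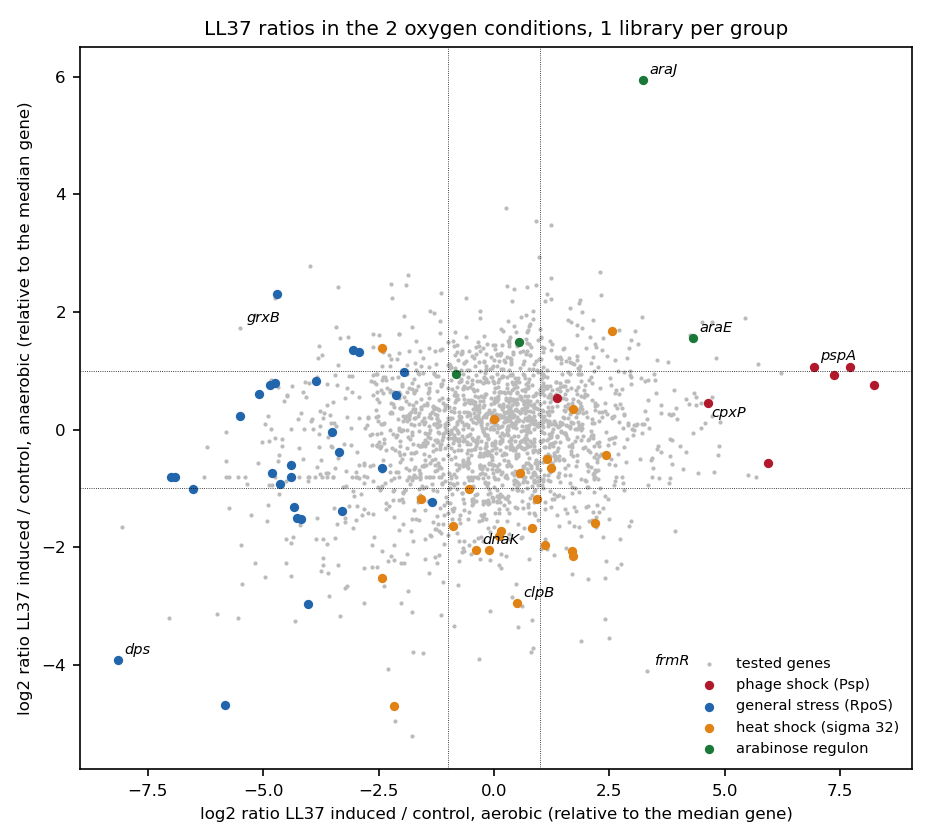
Each point is 1 of 2096 genes, with its log2 LL37 ratio relative to the median gene with air on the x axis and without air on the y axis, 4 gene lists in color and dotted lines at 2-fold. Phage shock genes lie far right near the middle of the y axis (pspA at 6.94 and 1.07) and RpoS genes lie far left (dps at -8.14 and -3.92).

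The controls compare growth without and with air in the absence of induction, and their plasmid labels differ as well. Nucleotide biosynthesis was the highest list: 12 of 13 purine and pyrimidine genes were higher and 1 lower (median 2.79, percentile 100), with guaB higher by 2.95 on log2 and purH by 2.79. Iron uptake genes had 7 of 8 higher (median 2.00, percentile 98.1), the PhoPQ and BasRS list 6 of 12 (median 1.25, percentile 97.1) and the sigma E list 6 higher and 7 lower of 28 (median 0.42, percentile 98.8). The cell separation gene nlpD (ECDH10B_2910), next to rpoS, went from 191 RPKM with air to 3731 without, 52.6-fold [95% interval 49.3 to 56.2] higher. The type II secretion gene gspH was 81.4-fold [95% interval 45.1 to 164] higher, yafX 54.1-fold [95% interval 35.4 to 87], the cold-induced lipid A gene lpxP 35.4-fold [95% interval 23.1 to 57.1] and the adenylate kinase gene adk 25.1-fold [95% interval 20.5 to 31.1]. The spermidine exporter gene mdtI had 2 reads with air and 103 without, a ratio of 98.1-fold [95% interval 26.5 to 821].

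Ribosome-associated and stationary phase genes were the lowest. Of 51 ribosomal protein genes, 41 were lower and 1 higher (median -3.94, percentile 0.04, or 2.9 among lists also matched on length). That median was -3.47 with members at 0 reads set to the read floor. Of 28 RpoS genes, 24 were lower and 1 higher (median -3.87, percentile 0.01). The hibernation factor gene rmf had 25984 reads in the aerobic control and 0 in the anaerobic control, at least 4548-fold lower, and sra was at least 1664-fold lower. The related gene raiA went from 13577 to 4.76 RPKM, 1059-fold [95% interval 576 to 2209.7] lower. Ribosomal protein genes rpmC (at least 729.7-fold) and rpsQ (428-fold [95% interval 208 to 1066]) were also low.

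Citric acid cycle genes were lower in 12 of 16 cases and higher in 2 (median -3.68, percentile 0.69), with gltA at 972 and 3.8 RPKM. Aerobic respiration genes were lower in 12 of 16 (median -1.92, percentile 1.05), with sdhA at -2.62 and cyoA at -1.28 on log2. Acid resistance (median -3.13, percentile 0.01), catabolite-controlled carbon use (-1.72, percentile 0.06) and the OxyR regulon (-1.55, percentile 4.31, or 7.27 over members on this list only) were low. The Rcs and colanic acid list was at -1.57 (percentile 3.0, or 5.39 among lists also matched on length and 14.8 over members on this list only), yet at 1.44 when libraries were scaled to the same sum (percentile 98.75) and 0.85 when that sum left out the top 1% of genes (percentile 82.75). Toxin-antitoxin genes had a median of -2.54 (percentile 0.375), which was unremarkable among lists also matched on length (percentile 52.1). The fermentation list was unremarkable (7 of 15 lower, 2 higher, median -0.57, percentile 47.6), although adhE and pflB, at 2625 and 874 RPKM with air, were at 69.3 and 17.7 without. The nitrate reductase gene narG was higher by 1.72 on log2, within an anaerobic respiration list that stayed at percentile 77 (median 0.90). The oxygen regulator genes fnr and arcA were at -0.65 and -1.48 on log2, arcA at 0.28 among genes with a mean of at least 50 RPKM. As deposited, the median gene was at -1.43 on log2, with 256 genes at least 2-fold higher and 1225 lower, against 652 and 705 relative to the median gene. Of 42 lists, 4 lay above the 95th and 9 below the 5th percentile.

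With LL37 induced, purine and pyrimidine genes were again high (10 of 13, median 2.45, percentile 100), and the BaeSR list was at 2.02 over 4 genes (percentile 97.7). Of 15 tested anaerobic respiration genes (37 on the list), 12 were higher and 2 lower without air (median 1.78, percentile 99.6), with narG higher by 3.42 on log2. Hydrogenase genes had 10 of 17 higher and 1 lower (median 1.19, percentile 95.2, or 94.8 among random lists of genes above the read floor), with hybB at 3 and 595 reads, a ratio of 90.7-fold [95% interval 30.9 to 441]. The cytochrome bd list, the oxidases used at low oxygen, had 3 of 4 higher (median 1.59, percentile 98.1), with cydA higher by 2.00 on log2 and appC by 3.35. Whether these lists differ between the control and LL37 pairs was not tested. The genes gspH (63.8-fold [95% interval 24.8 to 235]), nlpD (30.9-fold [95% interval 26.2 to 36.7]), araJ (33.7-fold [95% interval 23.9 to 49]) and accA, for fatty acid synthesis (33.2-fold [95% interval 18.9 to 64.5]), had some of the highest ratios.

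The phage shock list was the lowest, at a median of -6.69 with 6 of 7 genes lower (percentile 0.04), and pspA was 190.1-fold [95% interval 161 to 226] lower without air. Toxin-antitoxin (11 of 13 lower, median -3.99, percentile 0) and heat shock genes (14 of 24 lower, -1.68, percentile 3.67) were low, as were Cpx (11 of 19, -1.54, percentile 4.55, or 5.83 over members on this list only) and sigma E genes (17 of 28, -1.52, percentile 1.66). The methionine list was at -1.03 (percentile 2.49) and the branched chain amino acid list at -1.41 (percentile 4.69, or 9.93 among lists also matched on length and 6.33 over members above the read floor). Ribosomal protein genes had 36 of 51 lower (median -2.72, percentile 0.11, or 12.9 among lists also matched on length). That median was -2.36 with members at 0 reads set to the read floor. The lowest single ratios were those of short genes such as the toxin gene hokD (at least 258-fold), the leader peptide gene rhoL (at least 137-fold), yebG (at least 217-fold) and soxS (at least 171-fold), each with 0 reads without air.

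Lists near 0 also passed the percentile rule, because most matched random lists were lower. The outer membrane list was at 0.51 (percentile 98.3, or 92.2 matched on length), with ompA higher by 3.32 on log2. The RpoS list was at 0.069 (percentile 97.5) and glycolysis at 0.027 (percentile 95.2, or 81.5 matched on length), but neither passed when libraries were scaled to the same sum (-0.068 at percentile 70.15 and -0.15 at 74.95). The gene dps was at -1.48 on log2 against -5.67 in the controls, and cpxP at -4.48 against 0.013. As deposited, the median gene was at 0.99 on log2, with 1047 genes at least 2-fold higher and 389 lower, against 614 and 654 relative to the median gene. Of 42 lists, 8 lay above the 95th and 8 below the 5th percentile.

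**Figure D4:**
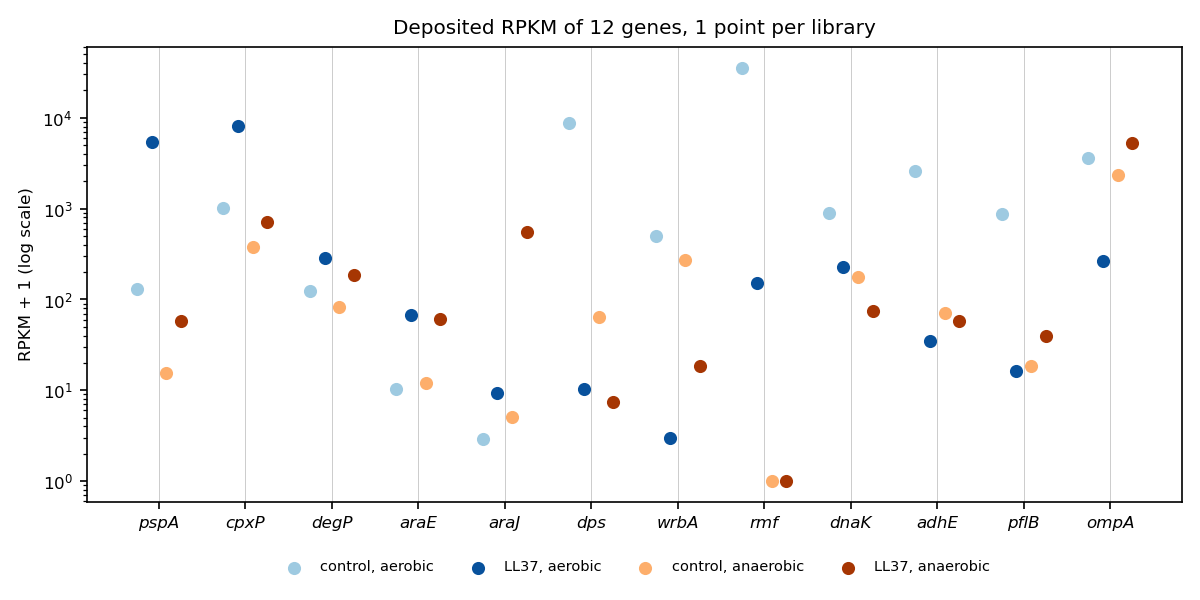
Deposited RPKM + 1 of 12 genes on a log axis, 1 point per library. The gene pspA reached 5377 RPKM in aerobic LL37, against at most 129.7 in the other libraries, and dps reached 8786 RPKM in the aerobic control, against at most 63.2 in the other libraries.

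The oxygen ratios of the control and LL37 pairs were correlated: across the 2096 genes the correlation was 0.61 (Pearson) and 0.59 (Spearman), and 0.51 (Pearson) over genes of at least 600 bp. Both ratios were at least 2-fold higher for 388 genes, where independent ratios would give 191, and at least 2-fold lower for 390, against 220. Purine and pyrimidine biosynthesis was above the 95th percentile in both pairs, and ribosomal proteins and toxin-antitoxin genes were below the 5th in both. Matched on length as well, neither of these low lists stayed below it in both (2.9 and 12.9, and 52.1 and 1.8). Other lists went apart. Sigma E was at percentile 98.85 in the controls and 1.66 with LL37, and phage shock at 91.7 and 0.04. RpoS was at 0.01 and 97.5, the latter 70.15 with libraries scaled to the same sum. In the limma fit over all 4 libraries, 22 genes fell without air and 0 rose on the deposited scale, and all 22 were shorter than 600 bp. On other scales genes also rose: 71 rose and 261 fell with median-of-ratios scaling, 197 and 197 with quantile normalization, 16 and 35 with the same sum without the top 1% of genes, and 5 and 55 when centred on the median gene. The prior degrees of freedom were infinite in the fit on the deposited scale, so each p rests on a variance pooled over genes, not on the spread of that gene. On that scale the LL37 ratios with and without air differed by a median of 2.40 on log2. The additive fit counts this offset as error, so its counts for LL37 and oxygen also carry the scaling of the libraries. Where the prior was smallest, 0 genes were called (prior 3.23 with the same sum, 3.46 over genes of at least 600 bp), against 51 at 4.96 without the top 1% of genes and 60 at 5.48 when centred. The smallest adjusted p was that of rmf (log2 change -11.18 on the deposited scale, SE 1.80, adjusted p 1.31e-06, lower in both pairs of libraries). The others with the smallest adjusted p were mokB, sra, hokD and rhoL, and the ribosomal protein genes rpmI, rpmD, rpsQ, rpmC and rpmG. Of the 22, 0 passed with libraries scaled to the same sum of RPKM or with a pseudocount of 10 RPKM, though all 22 stayed lower in both. For LL37, the limma fit called 0 genes (smallest adjusted p 0.9997). Of the 2096 genes, 28 had an unadjusted p under 0.05 in that fit, fewer than this threshold gives by chance. For LL37, the fit called 36 genes with libraries scaled by the median of ratios and 13 with quantile normalization.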

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

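Chosen only after the result was seen were the tests on the RpoS genes and the phage shock genes, the short-gene test within ribosomal operons, the read floor applied to the results below, and the condition that a difference within the fixed operons exceed its spread.

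Of 396 tested named genes, 362 were above the read floor in both oxygen conditions, and 34 of these were at least 2-fold higher with LL37 in one condition and at least 2-fold lower in the other, relative to the median gene. As deposited there were 88, and 21 were in both sets. Those 21 include all of the genes lower in air and higher without air that are named below. Among all 2096 genes, 115 moved in opposite directions, fewer than the 164 that independent ratios would give. None of the differences between conditions was tested, since each group holds 1 library. In the values below, the log2 ratio with air comes first, then that without air, then the second minus the first. Ratios with 0 to 3 reads in a library, such as those of frmR, yihD and sufA, depend on the added 1 RPKM.

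The 16 genes higher with LL37 in air and lower without air include the sigma E operon: rpoE (1.99 and -1.32, difference -3.31), rseA (2.12 and -1.54, difference -3.66), rseB (2.21 and -1.65, difference -3.85) and rseC (2.68 and -2.35, difference -5.03). Other sigma factor genes among them were rpoH (2.20 and -1.59, difference -3.79) and rpoD (1.72 and -2.15, difference -3.87). Lipopolysaccharide transport genes were lptA (1.11 and -1.35, difference -2.45) and lptB (1.40 and -1.65, difference -3.05). The small heat shock protein gene was ibpA (1.69 and -2.07, difference -3.76). Genes of redox and formaldehyde responses were frmR (3.33 and -4.10, difference -7.43), soxR (2.41 and -3.22, difference -5.63) and nfsA (1.74 and -1.64, difference -3.37). The rest were exbD (2.03 and -2.54, difference -4.58), mazE (2.93 and -1.64, difference -4.57), metJ (2.36 and -1.82, difference -4.17) and sixA (2.73 and -1.86, difference -4.59). Of the 16, only frmR, sixA and rseC also met the rule as deposited. The others, rpoE, rpoH and rpoD included, met it only relative to the median gene, which was at -1.58 with air and 0.81 without.

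The 18 genes lower with LL37 in air and higher without air include grxB (-5.50 and 1.73, difference 7.22), elaB (-4.71 and 2.31, difference 7.02), yihD (-3.99 and 2.77, difference 6.77), raiA (-1.89 and 1.09, difference 2.98) and sufA (-4.74 and 2.24, difference 6.99). Acid resistance genes were gadB (-5.18 and 1.94, difference 7.12), hdeD (-3.43 and 1.75, difference 5.18) and slp (-3.37 and 1.09, difference 4.47). Cold shock genes were cspA (-2.44 and 1.08, difference 3.52) and cspG (-2.22 and 2.47, difference 4.69). Ribosomal protein genes were rplL (-2.40 and 1.33, difference 3.73) and rpsE (-1.12 and 1.36, difference 2.48). Metabolic genes were sdhB (-2.62 and 1.62, difference 4.24), ldhA (-2.42 and 1.39, difference 3.81), lsrF (-3.17 and 1.57, difference 4.74), putP (-2.25 and 1.08, difference 3.34), astB (-2.24 and 1.20, difference 3.43) and astD (-1.90 and 2.46, difference 4.36). As lists, acid resistance was at -3.23 with air and 0.50 without (difference 3.73), and heat shock at 0.54 and -1.62 (difference -2.15). As deposited, acid resistance was at -4.81 and 1.31, whereas heat shock was at -1.05 and -0.81, lower in both. Heat shock thus moved in opposite directions only relative to the median gene. With air, its median was also -0.0089 without the filter and -0.0051 over genes of at least 600 bp.

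The first pattern weighed is the scarcity of short genes in both anaerobic libraries. A change confined to ribosomal protein and RpoS genes is argued against among the tested genes: 134 short genes on neither list had a median oxygen ratio of -3.73 in the controls and -2.97 with LL37. These genes passed the same filter on mean RPKM, which favours genes high in the aerobic control. Gene length as such was tested inside 8 fixed operons. Short members minus long members gave a median of 0.29 with an SD of 1.85, from -2.66 to 3.79. This lay past the bound set in advance against length but by less than that SD, so it does not decide. The short members there were not limited to genes below 300 bp. Across tested genes of 300 to 600 bp, the median oxygen ratio was -0.66 in the controls and -0.61 with LL37. Below 300 bp it was -3.87 and -3.04. The operon test therefore covers the scarce length class only in part. Within the S10 and spc ribosomal operons, 4 members below 300 bp were compared with 4 of at least 600 bp in the controls. Their medians differed by -5.49 on log2, with a standard error for the difference in means of 1.42. An effect of gene length on fragments or counting could give this. However, these operons were chosen after low ratios of ribosomal protein genes had been seen, so the difference is no independent support for length. Their genes share transcripts and libraries, so the standard error does not measure a spread between cultures. The fixed operons were judged against an SD and the ribosomal operons against a standard error, so the outcomes do not rest on the same measure. Shorter half-lives or other RNA handling in these cultures were not tested.

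The second pattern is the low level of all 28 RpoS genes in aerobic LL37. Gene length is argued against, since 13 members of at least 600 bp had a median of -4.17. The list was also lower in the anaerobic than in the aerobic control (-3.87), and at 0.069 between the LL37 libraries, so the aerobic control stands apart from the other 3 libraries. A later growth phase of the aerobic control and an effect of LL37 cannot be told apart, because each group is 1 culture and the labels used here give no growth phase. The plasmid, which also differs in the aerobic pair, stays open as well: in the anaerobic pair, with the same plasmid, the list was at -0.70 with LL37 (9 of 28 lower, 3 higher, percentile 7.84).

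The third pattern is the phage shock response, much higher with LL37 in air (list median 6.94) than without (0.76). Absence of induction without air is argued against by the arabinose genes, whose median lay at percentile 99.9 there, though the LL37 transcript itself was not measured. Loss of short genes without air is argued against for pspA, the 1 member of the operon pspABCDE of at least 600 bp, which itself differed by -5.87 between conditions. The oxygen ratio of 4 short members of that operon lay above that of pspA by 1.28 with LL37 (SD 0.92) and 1.60 in the controls. These 4 members were not all below 300 bp, so their comparison covers the scarce length class only in part. For pspG, outside the operon, such a loss cannot be told apart, because the oxygen ratio of pspG in the controls (-0.62) rests on 4 reads without air. The phage shock genes may thus respond more to LL37 in air, as a hypothesis that 1 library per group and the plasmid difference in the aerobic pair leave untested.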

How the results depend on the processing

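The alternatives chosen only after the result was seen were centring on the median gene, genes of at least 600 bp, random lists matched on length, lists without members at the read floor, and recovered reads. Counts of genes past 2-fold followed the scale of the libraries, and so did their balance between higher and lower. As deposited, the genes higher and lower were 131 and 1346 for LL37 with air, 852 and 120 for LL37 without air, 256 and 1225 for oxygen in the controls, and 1047 and 389 for oxygen with LL37. The same 4 pairs of counts follow for each alternative. With a pseudocount of 0.1 RPKM they were 137 and 1399, 917 and 143, 271 and 1241, and 1066 and 410. With a pseudocount of 10 RPKM they were 84 and 1054, 385 and 50, 125 and 1014, and 756 and 261. Without the filter on low values they were 237 and 2001, 1657 and 184, 413 and 1991, and 1868 and 661. With a mean of at least 50 RPKM they were 41 and 397, 138 and 67, 46 and 399, and 164 and 178. Scaled by the median of ratios they were 434 and 696, 186 and 393, 466 and 807, and 465 and 761. Scaled to the same sum of RPKM they were 952 and 462, 636 and 254, 1404 and 415, and 1306 and 430. Scaled to that sum without the top 1% of genes they were 728 and 541, 458 and 302, 1128 and 491, and 1087 and 463. Under quantile normalization they were 537 and 542, 371 and 444, 730 and 605, and 731 and 685. Centred on the median gene they were 543 and 615, 255 and 344, 652 and 705, and 614 and 654. Over centred genes of at least 600 bp they were 347 and 392, 153 and 207, 455 and 428, and 404 and 415. At 4-fold they were 54 and 842, 184 and 33, 84 and 831, and 614 and 213. On recovered reads with an exact interval past 2-fold they were 86 and 1081, 478 and 48, 167 and 1071, and 792 and 218. The scaling alternatives move the median gene by construction, and the stricter filter tests fewer genes; other causes were not tested.

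The limma fit called 22 genes for oxygen, all lower. The count was 0 with a pseudocount of 10 RPKM, 7 with a mean of at least 50 RPKM, 332 (71 higher) with median-of-ratios scaling, 0 with the same sum, 51 (16 higher) with that sum without the top 1% of genes, 394 (197 higher) with quantile normalization, 60 (5 higher) with centring, 0 with genes of at least 600 bp, 53 (1 higher) with no trend, and 34 (1 higher) with a threshold of 0.10. The 22 genes stayed lower in every alternative that tested them, and still passed in 18 cases with a pseudocount of 0.1 RPKM, 21 with the sum without the top 1% of genes, 6 with a mean of at least 50 RPKM and 0 with a pseudocount of 10 RPKM or the same sum. Genes of at least 600 bp hold none of them, and there the fit called 0 genes. For LL37 the count was 0, against 36 with median-of-ratios scaling and 13 with quantile normalization, and it stayed at 0 in the other alternatives. 

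The correlation of the LL37 ratios across genes, 0.17, was 0.12 with a pseudocount of 0.1 RPKM, 0.25 with 10 RPKM, 0.23 with a mean of at least 50 RPKM and 0.13 under quantile normalization. That of the oxygen ratios, 0.61, was 0.57 with a pseudocount of 10 RPKM, 0.57 without the filter, 0.58 with median-of-ratios scaling and 0.51 over genes of at least 600 bp. The genes whose LL37 ratio differed by at least 4-fold between oxygen conditions numbered 1271 as deposited, 790 with a pseudocount of 10 RPKM, 1955 without the filter and 350 with a mean of at least 50 RPKM. They numbered 648 with median-of-ratios scaling, 701 with the same sum, 669 without the top 1% of genes, 675 under quantile normalization, 620 when centred and 367 over genes of at least 600 bp. The cause was not tested beyond the smaller number of genes in the stricter filters.

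Of the 63 list medians past a percentile threshold, 63 stayed past it on the same side with a pseudocount of 0.1 RPKM, 55 with 10 RPKM, 50 without the filter and 23 with a mean of at least 50 RPKM, where 25 list medians in all passed. At that mean only 72 list medians had enough members for a percentile, against 168 at first and 140 over genes of at least 600 bp. Those that could not be placed are not lost calls. The scalings kept 54, 49, 50 and 46 (median of ratios, same sum, that sum without the top 1% of genes, quantile). Lists were centred on the median gene again in each alternative, so a scaling factor per library largely cancels. Apart from quantile normalization, the scalings could move lists only through the pseudocount and the filter. On the deposited scale signs can differ: for LL37 with air, sigma E (1.05) was at -0.53 and Cpx (0.80) at -0.78. Genes of at least 600 bp kept 37, members on 1 list only 58, length-matched random lists 55 and members above the read floor 59. These medians changed sign. For oxygen with LL37, the RpoS list (0.069) was at -0.12 with a pseudocount of 10 RPKM, -0.22 without the filter, -0.068 with the same sum and -0.033 without the top 1% of genes, and glycolysis (0.027) at -0.15, -0.12 and -0.22 with the same sum, without the top 1% of genes and over genes of at least 600 bp. For oxygen in the controls, the Rcs list (-1.57) was at 1.05 without the filter, 1.44 with the same sum and 0.85 without the top 1% of genes. For LL37 with air, heat shock (0.54) was at -0.0089 without the filter and -0.0051 over genes of at least 600 bp, and the arabinose list (1.89) at -0.0025 without the filter. For LL37 without air, ribosomal proteins (-0.16) were at 0.29 with a mean of at least 50 RPKM, 0.10 with median-of-ratios scaling and 0.055 under quantile normalization, toxin-antitoxin genes (-0.81) at 0.075 with a mean of at least 50 RPKM and 0.10 with median-of-ratios scaling, and cold shock (0.68) at -0.13 over genes of at least 600 bp. Of these, heat shock without the filter (percentile 99.35) and ribosomal proteins with a mean of at least 50 RPKM (98.55) or median-of-ratios scaling (99.95) stayed past the threshold on the same side. The Rcs list passed on the other side without the filter (99.95) and with the same sum (98.75), and the rest lay inside the thresholds. The cause was not tested, apart from the toxin-antitoxin members at the read floor.

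For 218 ratios of named genes, 1522 of 1759 alternative values lay within the spread seen inside operons, 232 moved by more and 5 changed sign. These values were centred on the median gene in each alternative as well, so a scaling factor per library largely cancels in them. The oxygen ratio in the controls was 0.12 for pspA, 0.26 for lexA and 0.28 for arcA with a mean of at least 50 RPKM, the oxygen ratio with LL37 was 0.011 for degP under quantile normalization, and the LL37 ratio without air was -0.056 for slp with a pseudocount of 10 RPKM. The cause was not tested. With 1 library per group, no library could be left out and no other splits of the samples were counted. Depth limits what 0 reads can exclude: in a gene of 1 kb, up to 0.690 RPKM in the aerobic control, 0.887 in aerobic LL37, 0.488 in the anaerobic control and 0.807 in anaerobic LL37. The scarcity of short genes did not follow depth: below 300 bp, 34.8% and 41.9% of the tested genes had 0 reads in the anaerobic control and LL37 libraries, against 0% and 5.16% in the aerobic control and LL37 libraries, although the anaerobic control had the highest read total (6149126). The value of 0% can come in part from the filter on mean RPKM, which favours genes high in the aerobic control.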

Other observations

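The tests behind the arabinose hypothesis below were chosen only after the result was seen.

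Several lists stayed inside the percentile thresholds in the LL37 comparisons. With air, the list of peptide uptake genes and peptidases had 7 of 22 genes higher and 5 lower (median -0.021, percentile 47.2), although yejA, which encodes the binding protein of the Yej transporter, was higher by 3.00 on log2. SOS response genes had a median of 0.29 with air (percentile 76.8) and -0.29 without (percentile 21.7). Peptidoglycan and cell division genes were at 0.26 (percentile 59.6) and -0.17 (percentile 17.7), and ATP synthase genes at -0.79 (percentile 55.2) and -0.19 (percentile 67.3). The MarA, SoxS and Rob regulon was at 0.73 with air (percentile 93.8, or 96.2 over members on this list only), with marR higher by 4.83 and marA by 2.63 on log2. The gene for the sigma factor RpoS itself was at 1221 RPKM in the aerobic control, 161 in aerobic LL37, 237 in the anaerobic control and 176 in anaerobic LL37. The oxygen sensor gene fnr was at 117, 418, 27 and 33.2 RPKM in the same order.

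The vector is inducible by arabinose, although the labels do not name the inducer. If the LL37 cultures had received arabinose, the arabinose genes should be higher in both and other sugar genes under catabolite control should not. The arabinose list lay at percentile 98.4 with air and 99.9 without, while the catabolite-controlled list lay at percentile 0 and 1.76. With air, however, the percentile was 72.2 without the filter on low values, 68.0 with libraries scaled to the same sum and 63.5 when that sum left out the top 1% of genes, so arabinose as the inducer stays open there. The list holds 4 genes per comparison: araE was higher in both (log2 4.31 and 1.56), as was araJ (3.23 and 5.95), but araF was not (-0.82 and 0.95).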
